A study of Mus musculus with 12 samples.

How the data were processed

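Per the labels' protocols, male C57BL/6N mice aged 12 weeks received 50 nl of 20 mM kainate, an agonist of glutamate receptors, in the left dorsal hippocampus. They developed recurrent seizures and, 3 weeks later, were given 1 intraperitoneal injection of saline or of lipopolysaccharide (LPS, a component of the outer wall of Gram-negative bacteria) at 100 µg/kg. Hippocampi were dissected 4 or 24 h after it, with 3 mice per group in the labels. The labels state neither which side was used nor the hour of day, and no group of mice without kainate is part of the series. Per the labels' protocols, only RNA with a high integrity number was labelled with Cy3 and hybridised to one-colour Agilent arrays, of which there are 12.

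The deposited per-array files give the fluorescence intensity of 45018 spots. Per the file headers, Agilent Feature Extraction 10.7.3.1 subtracted the background, removed spatial trends and put a surrogate value in place of spots too dim to measure, and nothing was scaled between arrays; the submitters' processing notes name version 9.1 of the same software. The deposited series matrix holds log2 values whose medians per array run from 6.98 to 6.99. Those log2 values were recomputed here from the deposited raw intensities with normexp background correction (offset 50) followed by quantile normalization, with a largest difference of 4.5e-10.

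The processed intensity of the 43379 spots of transcript probes was taken as log2, 12 outlier spots were left out, repeated spots of a probe were averaged, and the 75th percentile of each array was subtracted. A probe entered when its signal was called well above background on all 3 arrays of at least 1 group, which left 27683 of 41174 probes. Probes were named through the RefSeq table by accession (27479 probes), by current symbol (5478) or by synonym (679), and 7538 kept the name in the files. Each gene was represented by its probe with the highest mean signal, which gave 18179 features (called genes from here on), 15056 of them with a plain symbol. Positions are those of the probes on the mouse build that the files use, mm9.

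Means of the 4 groups were fitted in 1 linear model over all 12 arrays with limma 3.58.1 in R 4.3.3, with its empirical Bayes moderation. A gene was called higher or lower at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and every adjusted p of a single gene is from this two-sided test. The comparisons were LPS against saline at 4 h and at 24 h, the difference between these responses, and saline at 24 h against saline at 4 h. Values are log2 differences with the standard error (SE) of the fit. Where a gene was not well above background on any array of its dimmer group, the fold is given as "at least", computed against the lowest signal called well above background on each array of that group, or the gene's own signal where that was higher. No fold is given where both groups are below background.

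A set of 34 gene lists with 579 entries, 549 of them measured, covers inflammation, vascular activation, stress, neuronal signalling, metabolism, the clock, cell types and neighbouring tissues. Each list was tested against all other genes with camera in limma (inter-gene correlation preset to 0.01, Benjamini-Hochberg over the lists of a comparison) and again with the correlation estimated from the residuals. List medians are given relative to the median of all genes, because that median moved with the scaling. Where a value is called a median without mention of all genes, it is the list's own. Of the measured members, 21 are in more than 1 list. Named genes are, per LPS comparison, the 12 largest rises and 8 largest falls with a plain symbol and non-overlapping arrays, up to 4 members per list with the smallest adjusted p, and 12 genes that are always named. For the difference between times the 6 largest of each sign are named, and for the saline comparison the 5 largest of each sign. Lists, comparisons, tests, filter and naming rule, and the alternatives not said to be added, were fixed before the data were examined.

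The procedure was tested on simulated data with 18179 genes. At 4 h it recovered 78 of 100 genes changed 1.5-fold and 89 of 100 changed 2-fold, with 9 calls among the unchanged genes; at 24 h it recovered 77 of 100 and 86 of 100, with 5. Both of the 2 shifted lists were called at each time, and 0 others. Apart from the planted changes, the simulated noise was independent between genes and arrays, with no shift of a group, slide or run. These counts therefore do not tell how many calls such shifts give in the real arrays. Alternatives covered background correction, scaling, the deposited matrix, the filter, the probe rule, the arrays in the fit, blocks by replicate number and by slide, moderation, array weights, thresholds and leaving out each array. The saline arrays of the other time were added as controls after the data were seen.

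The arrays came from 6 slides, each with 1 saline and 1 LPS array of the same time, in 2 scan runs: 1 run holds all arrays of 4 h and the other all of 24 h. Time and run cannot be told apart for this reason. On genes with 1 spot that were detected on all arrays, the median SD between the 3 arrays of a group was 0.04 to 0.06 log2 units. Between the 10 spots of repeated probes within an array it was 0.05 to 0.09. The spread that the tests use was thus of the size of the measurement error of an array. Every SE and p value here rests on that spread, and how far it covers variation between mice cannot be told.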

Results

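Gene expression was measured in 12 samples of hippocampus from mice with recurrent seizures after kainate, 3 in each of 4 groups: saline at 4 h, LPS at 4 h, saline at 24 h and LPS at 24 h. The 75th percentile of the processed intensity was 385 ± 12.4 (SD, n = 3) in saline 4 h, 702 ± 35.7 in LPS 4 h, 798 ± 61.3 in saline 24 h and 864 ± 124 in LPS 24 h. In the same order, 54.6%, 59.6%, 65.6% and 69.8% of transcript probes were well above background, and 0 spots were saturated. The median SD between the 3 arrays of a group was 0.04 to 0.06 log2 units, against 0.05 to 0.09 between repeated spots on 1 array, so that the arrays come from separate animals rests on the labels alone. The saline arrays, from mice that had also received kainate, are the background for every LPS value.

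The first comparison asks which hippocampal genes differ 4 h after LPS in mice with seizures. Transcripts of chemokines, interferon-induced genes and acute phase proteins were far above saline at that time, and single endothelial genes such as Sox17 and Cldn5 were below it. Cxcl1, a chemokine that attracts neutrophils (probe on chromosome 5, 91321845 to 91321904), rose at least 20.1-fold (n = 3 per group, adjusted p = 5.27e-10). Saa3, a serum amyloid A protein of the acute phase (chromosome 7, 53968031 to 53968090), rose at least 70.4-fold, and Csf3, the growth factor of granulocytes, at least 15.7-fold, with adjusted p values of 2.88e-10 and 1.09e-10. Il1b, which encodes interleukin-1 beta, rose by 3.11 ± 0.04 (SE) on the log2 scale (adjusted p = 1.72e-11). Sox17, a transcription factor of endothelium, fell by 3.64 ± 0.06 and Cldn5, a tight junction protein of the blood-brain barrier, fell by 3.08 ± 0.07, with adjusted p values of 6.10e-11 and 2.86e-10.

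The other genes among the 12 largest fitted rises at 4 h were Clec4e, a receptor of macrophages (at least 8.78-fold), the protease inhibitor Serpina3f (at least 8.11-fold), the chemokine Cxcl11 (at least 24.1-fold), Mefv, which encodes pyrin (at least 8.79-fold), coagulation factor F10 (at least 7.38-fold), the RNA-binding protein Rbm47 (at least 6.74-fold), the interferon-induced Rsad2 (4.60 ± 0.05), the chitinase-like Chil3 (4.22 ± 0.06) and the kinase anchor Akap12 (4.18 ± 0.04). Their adjusted p values ran from 1.52e-11 for Rsad2 to 1.81e-06 for Mefv. Among the 8 largest fitted falls were 3 genes of anterior pituitary hormones: Cga (at least 5.46-fold lower), Gh (at least 3.91-fold lower) and Prl, which fell by 3.83 ± 0.14. The others were endothelial Myct1 (at least 4.79-fold lower), the keratin Krt33a (at least 4.92-fold lower) and the sphingolipid enzyme Degs2, which fell by 2.88 ± 0.07. Against the saline arrays of 24 h, a comparison added after the data were seen, all 8 stayed called lower. Prl was -0.712 there, and the fitted values of Cga, Gh and Krt33a were -1.93, -1.20 and -0.689, which are no measured folds. Against saline 4 h, the adjusted p values of the falls were between 6.10e-11 and 0.000388. For these genes, and for every gene named below as changed at 4 h, all 3 LPS arrays lay beyond all 3 saline arrays.

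Of 18179 genes tested, 5321 were higher and 8092 lower after LPS at 4 h, which is 13413 in all. At least 2-fold, 1345 were higher and 810 lower. The median change of all genes was -0.15, and it ran from -0.04 to -0.18 under other scalings. Most medians of lists are for this reason given relative to that of all genes. With the deposited matrix, 528 genes were at least 2-fold higher and 218 lower. With slide as a block, where each slide holds 1 saline and 1 LPS array, 13463 genes passed. Of 6777 genes with several probes, 1163 had probes called in both directions, so that a direction rests on the probe chosen. Against the saline arrays of 24 h, a comparison added after the data were seen, the balance turned to 7544 higher and 5748 lower.

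Cytokines and chemokines rose as a list at 4 h, with 15 of 20 measured members higher, 3 lower and 2 neither (median 1.33 above all genes, adjusted p = 6.23e-05). Ccl2, which recruits monocytes, rose by 2.72 ± 0.06 and Cxcl10, a chemokine induced by interferon, by 2.59 ± 0.05. Il6 was at least 4.47-fold higher (adjusted p = 2.10e-09) and Tnf at least 1.04-fold higher (adjusted p = 2.63e-07), although the sign of Tnf turned with another background correction. With 6 dim members at their bound, the median of the list itself was 0.73 in place of 1.18. Targets and feedback genes of NF-kappaB, the transcription factor downstream of LPS receptors, were higher for 13 of 17 and lower for 2 (0.78 above all genes, adjusted p = 0.00011). Among them were the subunit Nfkb2 (1.76 ± 0.04), Tnfaip2 (1.44 ± 0.06) and Icam1, an adhesion molecule (1.10 ± 0.04). Type I interferon response genes were higher for 20 of 24 and lower for 1 (1.21 above all genes, adjusted p = 3.76e-08). They include Oasl1 (2.50 ± 0.04) and Ifih1 (1.72 ± 0.03), a sensor of viral RNA. Acute phase proteins were higher for 9 of 13 and lower for 1 (1.98 above all genes, adjusted p = 0.000146). Examples are the iron-binding lipocalin Lcn2 at 4.01 ± 0.14, measured on 2 of the 3 saline arrays, and haptoglobin, Hp, at 2.88 ± 0.07. JAK-STAT feedback genes and receptors of the IL-6 family were higher for 11 of 15 and lower for 2 (1.04 above all genes, adjusted p = 0.00019). Socs3 is an example, an inhibitor of cytokine signalling (2.63 ± 0.03), and so is Il1rn, the natural antagonist of interleukin-1 (at least 4.40-fold, adjusted p = 4.39e-09).

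Pattern recognition and inflammasome genes were higher for 12 of 18 and lower for 1 at 4 h (0.64 above all genes, adjusted p = 0.000768, and adjusted p = 0.0724 with an estimated correlation). Cd14, the co-receptor of LPS, rose by 2.22 ± 0.04, the intracellular LPS sensor Casp4 by 2.19 ± 0.06 and Tlr4, the LPS receptor, by 0.88 ± 0.21 (measured on 2 of the 3 saline arrays). With normexp background correction and the same scaling the value of Tlr4 was 0.058 (adjusted p = 0.805). GTPases induced by interferon gamma and antigen presentation genes were higher for 11 of 19 and lower for 4 (adjusted p = 0.0292, and adjusted p = 0.0706 with an estimated correlation). They went both ways: the GTPase Gbp5 rose by 2.73 ± 0.05 while the class I antigen gene H2-K1 fell by 0.76 ± 0.03. Complement had 6 of 15 members higher, 7 lower and 2 neither (adjusted p = 0.719), with a median of -0.02 and a mean of 0.14. Against the saline arrays of 24 h this list passed as higher, with 13 higher and 1 lower (median 0.90, adjusted p = 7.19e-05). Its factor B gene, Cfb, rose by 1.47 ± 0.05.

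Genes of endothelial activation and prostaglandin synthesis were higher for 15 of 17 and lower for 2 at 4 h (0.98 above all genes, adjusted p = 4.10e-06). Among these were Ptgs2, the inducible cyclooxygenase (2.37 ± 0.08), and Thbd, thrombomodulin (1.08 ± 0.04). Markers of endothelium and the blood-brain barrier went the other way, with 14 of 19 lower and 2 higher (-0.32 against all genes, adjusted p = 0.0211, and adjusted p = 0.0584 with an estimated correlation). Besides Cldn5, the receptor tyrosine kinases Tek and Kdr fell by 2.52 ± 0.06 and 1.86 ± 0.03. With another background correction or a stricter filter this list no longer passed, at adjusted p values of 0.0628 and 0.0513, nor did it against the saline arrays of 24 h (adjusted p = 0.119), where Cldn5, Tek and Kdr stayed lower at -1.93, -2.29 and -1.62. Genes induced by glucocorticoids were higher for 14 of 17 and lower for 1 (1.04 above all genes, adjusted p = 4.10e-06). They include the lipid droplet protein Plin4 (2.88 ± 0.04), Cdkn1a, an inhibitor of the cell cycle (2.57 ± 0.05), and Fkbp5, a regulator of the glucocorticoid receptor (1.90 ± 0.04). Pericyte and smooth muscle markers were split with 5 of 12 higher and 5 lower (adjusted p = 0.484): Rgs5, a regulator of G proteins, rose by 0.75 ± 0.05 and the receptor Pdgfrb fell by 0.59 ± 0.05.

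Reactive astrocyte genes were higher for 14 of 24 and lower for 7 at 4 h (0.72 above all genes, adjusted p = 0.00149), with ceruloplasmin, Cp, at 1.83 ± 0.03 and Gbp2 at 2.40 ± 0.03. Gfap, the filament protein of astrocytes, went against them and fell by 1.00 ± 0.05, while another probe of Gfap was called in the opposite direction and the mean of its probes was -0.062 (adjusted p = 0.309). General astrocyte markers had 7 of 14 higher and 5 lower (adjusted p = 0.207), with the transcription factor Sox9 at 0.75 ± 0.03 and the calcium-binding S100b at -0.78 ± 0.05. With quantile normalization S100b was -0.108 (adjusted p = 0.106) and with the deposited matrix -0.086 (adjusted p = 0.147). Microglia and macrophage activation genes were higher for 12 of 18 and lower for 5 (adjusted p = 0.0337, and adjusted p = 0.0724 with an estimated correlation). The co-stimulatory receptor Cd40 rose by 3.01 ± 0.08, but Clec7a, a receptor for fungal glucans, fell by 0.99 ± 0.04. Of the resting-state microglia markers, 3 of 14 were higher and 8 lower (adjusted p = 0.339). The fractalkine receptor Cx3cr1 fell by 1.30 ± 0.04 and Aif1, a marker of microglia, fell by 0.83 ± 0.03, whereas the purine receptor P2ry12 was 0.13 ± 0.10 (adjusted p = 0.275). Against the saline arrays of 24 h, Cx3cr1 stayed lower at -1.18, but Aif1, Clec7a and Gfap turned higher, at 1.44, 0.64 and 0.73. Markers of neutrophils and blood monocytes were higher for 9 of 12 and lower for 1 (1.83 above all genes, adjusted p = 0.00116). S100a9 and S100a8, calcium-binding proteins of myeloid cells, rose by 3.71 ± 0.05 and 3.08 ± 0.15, S100a8 being measured on 1 of the 3 saline arrays. The median of the list itself was 0.55 in place of 1.69 with 3 dim members at their bound. Lymphocyte markers were lower for 9 of 14 and higher for 1 (adjusted p = 0.289), with Cd79b of B cells falling by 1.07 ± 0.05.

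Voltage-gated channel genes were higher after LPS at 4 h for 16 of 23 and lower for 3 (0.83 above all genes, adjusted p = 0.00019), and adjusted over the list alone 17 were higher and 4 lower. Hcn2, a pacemaker channel, rose by 1.14 ± 0.03. Glutamate receptors and transporters were higher for 12 of 22 and lower for 4 (0.35 above all genes, adjusted p = 0.0156), including the metabotropic receptor Grm5 (1.31 ± 0.05) and the vesicular transporter Slc17a7 (1.14 ± 0.06). Markers of hippocampal excitatory neurons were higher for 9 of 16 and lower for 4 (adjusted p = 0.0488, and adjusted p = 0.0898 with an estimated correlation). The kinase Camk2a rose by 1.01 ± 0.03 and Bok, of the BCL2 family, fell by 1.22 ± 0.03. The list did not pass without saline 4 h replicate 2, saline 4 h replicate 3 or LPS 4 h replicate 3, at adjusted p values of 0.0553, 0.0529 and 0.0529. Against the saline arrays of 24 h in place of those of 4 h, a comparison added after the data were seen, the channel list turned lower. Its own median was then -0.70, and that of all genes 0.058. Excitatory neurons turned lower (median -0.22, adjusted p = 0.0422) and glutamate receptors no longer passed (adjusted p = 0.663). Grm5, Slc17a7 and Camk2a turned to -1.11, -1.14 and -0.53. The cytokine list and the interferon list stayed higher. Beside these neuronal lists, 5 of 7 thalamic genes, a split made after the values were seen, had their highest mean in saline 4 h. Tcf7l2 stood at 2.94 there and 1.65 in LPS 4 h (log2), and Prkcd at 1.84 and 1.56. Lef1 and Slc17a6 were highest in LPS 4 h. With the mean of its probes the change of Tcf7l2 was 0.105 (adjusted p = 0.467). Whether tissue content differed between the 4 h groups was not tested.

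Among the lists that did not pass at 4 h, GABA receptors and synthesis had 11 of 20 higher and 7 lower, and interneurons 7 of 15 higher and 4 lower (adjusted p values of 0.196 and 0.212). The chloride transporter Slc12a2 rose by 1.31 ± 0.04 and the receptor subunit Gabrd fell by 1.24 ± 0.04, while Reln, an extracellular protein, and the neuropeptide Cck went apart, at 1.11 ± 0.05 and -1.02 ± 0.03. Immediate early and activity-regulated genes had 7 of 19 higher and 11 lower, and heat shock and ER stress genes 7 of 16 higher and 5 lower (adjusted p values of 0.561 and 0.289). Bdnf, a neurotrophin induced by activity, fell by 1.31 ± 0.04 and the transcription factor Egr4 fell by 1.49 ± 0.05, whereas Pdia4, an enzyme of protein folding, rose by 1.89 ± 0.04. With the saline arrays of 24 h as controls Bdnf and Egr4 turned higher, at 0.39 and 1.44. The heat shock list passed under quantile normalization, at an adjusted p of 0.00589, and astrocyte markers at 0.0121. Cholesterol synthesis (5 of 16 higher, 9 lower), oligodendrocytes (3 of 12 higher, 7 lower), and their precursors (2 of 10 higher, 7 lower) had adjusted p values of 0.758, 0.719 and 0.393. Hmgcs1, an enzyme of cholesterol synthesis, rose by 1.32 ± 0.03, the myelin enzyme Cnp rose by 1.45 ± 0.04 and Olig2, a transcription factor of the precursors, fell by 0.91 ± 0.05. Oxidative stress and the kynurenine pathway (6 of 13 higher, 5 lower) and the circadian clock (8 of 15 higher, 6 lower) had adjusted p values of 0.484 and 0.289, with the oxidase subunit Cyba at 1.13 ± 0.07 and the clock factor Npas2, measured on 2 of the 3 saline arrays, at 1.47 ± 0.10. With normexp and the same scaling Npas2 was 0.328 (adjusted p = 0.136). Red blood cell markers were lower for 6 of 7 and higher for 0 (-0.58 against all genes, adjusted p = 0.0292, and adjusted p = 0.275 with an estimated correlation). The globin gene Hbb-bt fell by 1.49 ± 0.04. This list no longer passed with the deposited matrix (adjusted p = 0.0875). Choroid plexus and ependyma (4 of 13 higher, 7 lower), meningeal fibroblasts (5 of 13 higher, 5 lower) and neighbouring brain regions (6 of 17 higher, 8 lower) had adjusted p values of 0.620, 0.624 and 0.878. Foxj1, a transcription factor of ciliated cells, fell by 0.90 ± 0.08 and the collagen gene Col1a1 rose by 1.31 ± 0.04. Median and mean had opposite signs for cholesterol synthesis (-0.19 and 0.10), meningeal fibroblasts (-0.10 and 0.18) and neighbouring brain regions (-0.28 and 0.01). In all, 15 of 34 lists were higher and 2 lower at 4 h, and 11 and 0 of them held with an estimated correlation. With the saline arrays of 24 h as controls, further genes named above were called in the other direction. H2-K1 (1.69), Bok (0.954), S100b (0.886), Pdgfrb (0.848), Cd79b (0.601) and Gabrd (0.166) were then higher, and Thbd (-0.430), Cnp (-0.424), Col1a1 (-0.381) and Rgs5 (-0.255) lower. Npas2, Sox9, Olig2, Cck, Foxj1 and Hbb-bt were called in neither direction there, at adjusted p values of 0.0633 to 0.774.

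**Figure D1:**
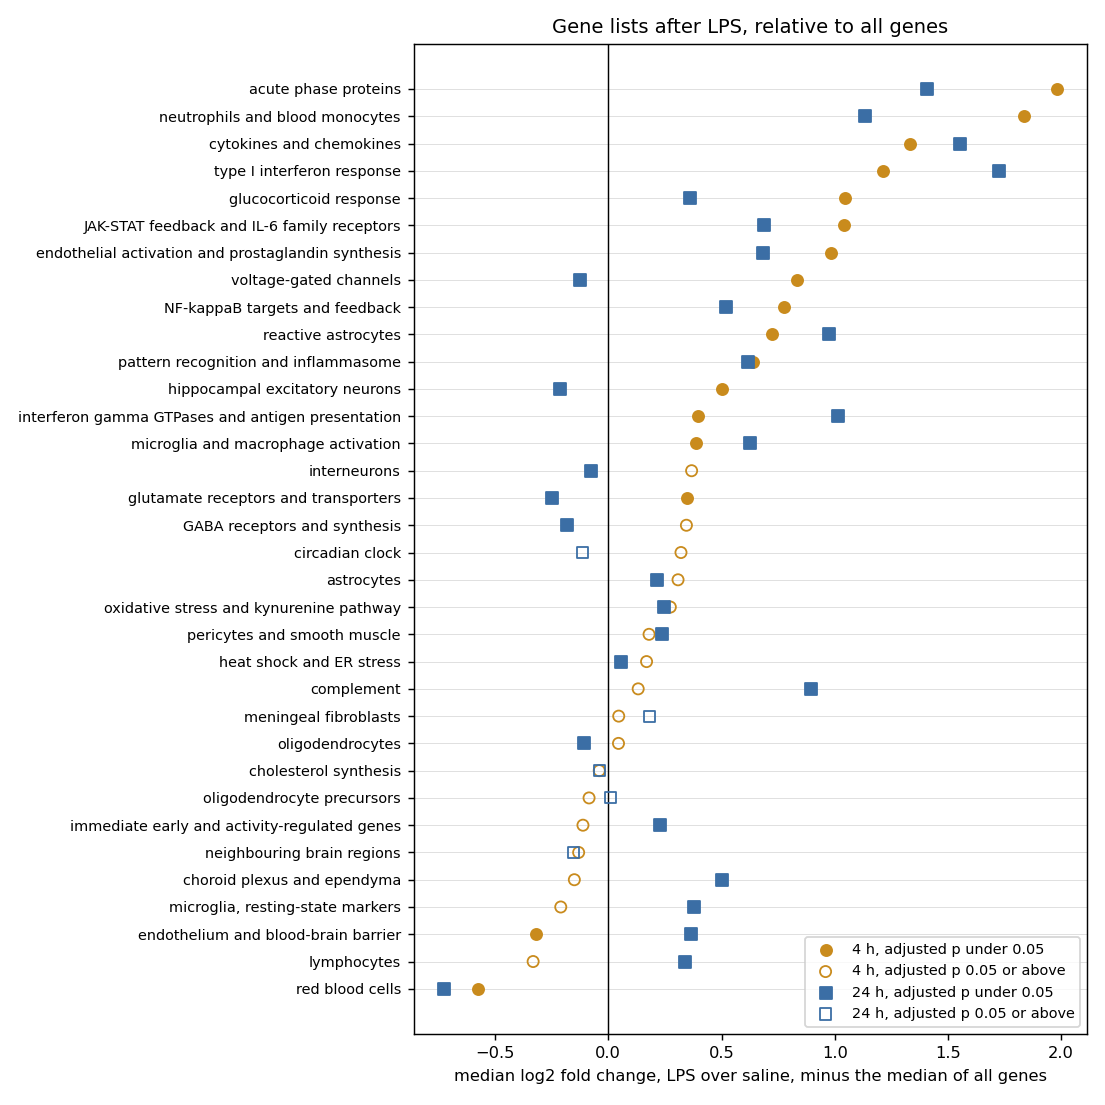
Median log2 change after LPS of each of the 34 gene lists minus the median of all genes, at 4 h (circles) and 24 h (squares), with filled symbols for an adjusted p under 0.05 in camera. Inflammation lists lie on the right at both times, and voltage-gated channels lie at 0.83 at 4 h and -0.12 at 24 h.

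The second comparison asks what differs 24 h after LPS. Interferon-induced genes, complement and markers of reactive glia were higher than in saline at that time, and receptors and channels of neurons were lower by small amounts. All 3 LPS arrays of each gene named below as changed lay beyond all 3 saline arrays. Saa3 had the largest fitted rise, at 7.21 ± 0.13 (n = 3 per group, adjusted p = 5.86e-10), with 1 of the 3 saline arrays well above background. Complement factor B, Cfb, rose 9.96-fold (3.32 ± 0.05, adjusted p = 2.65e-10) and Lcn2 7.70-fold (2.94 ± 0.14, adjusted p = 1.78e-07). Ido1, which starts the breakdown of tryptophan to kynurenine, fell by 2.91 ± 0.07 and Adora2a, the adenosine receptor enriched in striatum, fell by 2.59 ± 0.06, with adjusted p values of 2.41e-09 and 1.42e-09.

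The other genes among the 12 largest fitted rises at 24 h were the interferon-induced Ifi44 (3.17 ± 0.64), the B-cell chemokine Cxcl13 (3.16 ± 0.11), Ifi206 (3.04 ± 0.17), the antimicrobial lectin Reg3g (at least 1.94-fold), the homeobox gene Shox2 (at least 1.84-fold), Fam83g (at least 2.11-fold), the plasma glutathione peroxidase Gpx3 (2.86 ± 0.17), the receptor Cd244a of natural killer cells (2.77 ± 0.07) and Phf11a (2.77 ± 0.16). Their adjusted p values ran from 2.79e-09 for Cd244a to 0.00379 for Reg3g, and Ifi206 and Ifi44 were well above background on 1 and 2 of the 3 saline arrays. Also among the 8 largest fitted falls were the homeobox gene Lhx8 (at least 4.40-fold lower), the testis cytochrome Cyct (at least 2.48-fold lower), Prl, which fell by 2.49 ± 0.14, the lymphoid factor Ikzf3, which fell by 2.35 ± 0.11, and Gpr6, a receptor enriched in striatum, which fell by 2.23 ± 0.15. Their adjusted p values lay between 1.29e-07 and 0.00513. With normexp and the same scaling, Reg3g, Shox2 and Fam83g were 0.305, 0.337 and 0.387 on the log2 scale (adjusted p values of 0.445, 0.44 and 0.365), below the bounds given here, and such bounds do not rank these genes among the largest. In that setting Lhx8 and Cyct were -0.73 and -0.459 (adjusted p values of 0.0519 and 0.255), and with the deposited matrix Reg3g was 0.225 (adjusted p = 0.208).

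At 24 h, 4244 genes were higher and 4138 lower, 8382 in all, and at least 2-fold 541 were higher and 42 lower. With slide as a block 8238 genes passed, and 210 of the 6777 genes with several probes had probes called in both directions. Against the saline arrays of 4 h, 2339 genes were at least 2-fold higher and 2531 lower. With normexp background correction and the same scaling the total was 3410. With the deposited matrix, 153 genes were at least 2-fold higher and 17 lower.

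All 24 type I interferon response genes were higher at 24 h (1.73 above all genes, adjusted p = 1.43e-20). Examples are Oasl1 (2.71 ± 0.04), Zbp1, a sensor of nucleic acids (2.58 ± 0.04), and Isg15, a modifier of proteins (2.17 ± 0.04). GTPases induced by interferon gamma and antigen presentation genes were higher for 18 of 19 and lower for 0 (1.01 above all genes, adjusted p = 6.19e-13), including the GTPase Iigp1 (1.66 ± 0.04) and H2-D1 (1.30 ± 0.03). Complement was higher for 14 of 15 and lower for 0 (0.90 above all genes, adjusted p = 2.05e-11), and adjusted over the list alone for 15, with C3, its central component, at 1.28 ± 0.04 and the inhibitor Serping1 at 1.15 ± 0.03. Cytokines and chemokines were higher for 15 of 20 and lower for 1 (1.55 above all genes, adjusted p = 2.34e-10). Examples are the chemokines Ccl12 (2.57 ± 0.05), Ccl2 (2.44 ± 0.06) and Cxcl10 (2.38 ± 0.05), with Il1b at 1.70 ± 0.04 and Tnf at 1.42 ± 0.09, which 2 of the 3 saline arrays measured. With normexp and the same scaling Tnf was 0.305 (adjusted p = 0.373). With dim members at their bound the list's own median of 1.56 was 1.40. Il6 was below background in both groups at 24 h (adjusted p = 0.472). Acute phase proteins were higher for 10 of 13 and lower for 0 (1.41 above all genes, adjusted p = 3.80e-08), with the serum amyloid Saa2 at 2.36 ± 0.07 and ceruloplasmin, Cp, at 1.41 ± 0.03. NF-kappaB targets were higher for 15 of 17 and lower for 0 (0.52 above all genes, adjusted p = 3.13e-08), with Icam1 at 1.05 ± 0.04 and the co-regulator Bcl3 at 1.08 ± 0.05. Pattern recognition genes were higher for 16 of 18 and lower for 0, and adjusted over the list alone for 17 (0.62 above all genes, adjusted p = 1.64e-09). Tlr2, a receptor of bacterial lipoproteins, rose by 1.08 ± 0.03 and Cd14 by 0.49 ± 0.04, while Tlr4 was 0.50 ± 0.21 (adjusted p = 0.0766, and 0.0319 without LPS 24 h replicate 1). JAK-STAT feedback genes and IL-6 family receptors were higher for 13 of 15 and lower for 1 (0.69 above all genes, adjusted p = 4.89e-06), with Socs3 at 1.52 ± 0.03 and the receptor Il4ra at 1.27 ± 0.05.

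Reactive astrocyte genes were higher at 24 h for 22 of 24 and lower for 0 (0.97 above all genes, adjusted p = 1.80e-15). Serpina3n, a protease inhibitor, rose by 1.15 ± 0.02 and Gfap by 0.43 ± 0.05. Of this list, Serpina3n, Lcn2, Cp, Ptx3, Cxcl10, Gbp2, Cd14 and Osmr are also members of inflammation lists. At both times its rise is thus in part that of those lists. General astrocyte markers were higher for 9 of 14 and lower for 2, and adjusted over the list alone for 10 and 2 (adjusted p = 0.0135). The gap junction gene Gja1 went against them and fell by 0.52 ± 0.06. Microglia and macrophage activation genes were higher for 14 of 18 and lower for 2 (0.63 above all genes, adjusted p = 6.97e-06), among them the immunoglobulin receptor Fcgr4 (2.37 ± 0.07) and osteopontin, Spp1 (1.72 ± 0.03). Resting-state microglia markers were higher for 10 of 14 and lower for 1, and adjusted over the list alone for 10 and 3 (0.38 above all genes, adjusted p = 0.00248). Cx3cr1 rose by 0.71 ± 0.04, Tmem119 by 0.69 ± 0.03 and Aif1 by 0.82 ± 0.03, against P2ry12, which fell by 0.66 ± 0.10.

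Endothelial activation genes were higher at 24 h for 14 of 17 and lower for 1 (0.68 above all genes, adjusted p = 1.36e-07), with the secreted glycoprotein Lrg1 at 2.30 ± 0.03 and Vwf, the clotting protein of endothelium, at 0.78 ± 0.03. Markers of endothelium and the blood-brain barrier were higher for 14 of 19 and lower for 2 (0.37 above all genes, adjusted p = 1.13e-05), including Ly6a (1.66 ± 0.03) and the junction protein Esam (0.69 ± 0.03). Pericyte and smooth muscle markers were higher for 9 of 12 and lower for 0 (0.24 above all genes, adjusted p = 0.00352, and adjusted p = 0.0652 with an estimated correlation), with the calponin gene Cnn1 at 0.67 ± 0.05 and the peptidase Anpep at 0.53 ± 0.05. Genes induced by glucocorticoids were higher for 12 of 17 and lower for 2 (0.36 above all genes, adjusted p = 1.92e-05), with Plin4 at 2.66 ± 0.04 and the metallothionein Mt1 at 0.69 ± 0.03. Markers of neutrophils and blood monocytes were higher for 9 of 12 and lower for 0 (1.13 above all genes, adjusted p = 0.000418). Plac8, a gene of myeloid cells, rose by 2.53 ± 0.05 and S100a9 by 1.14 ± 0.05. The median of the list itself was 0.63 in place of 1.14 with 2 dim members at their bound. Lymphocyte markers were higher for 7 of 14 and lower for 1, and adjusted over the list alone for 8 and 1 (adjusted p = 0.00894, and adjusted p = 0.0505 with an estimated correlation). Cd8b1, of cytotoxic T cells, rose by 0.87 ± 0.05 and Cd79b by 0.75 ± 0.05. Choroid plexus and ependyma markers were higher for 11 of 13 and lower for 0 (0.50 above all genes, adjusted p = 1.37e-06), among them the bicarbonate transporter Slc4a5 (0.80 ± 0.05) and Tmem72 (0.97 ± 0.06). Red blood cell markers were lower for 6 of 7 and higher for 0 (-0.72 against all genes, adjusted p = 0.000159, and adjusted p = 0.0598 with an estimated correlation), with the globin genes Hba-a1 and Hbb-bt falling by 1.02 ± 0.04 and 0.89 ± 0.04. Meningeal fibroblast markers had 5 of 13 higher and 2 lower (adjusted p = 0.0804) and passed with the deposited matrix (adjusted p = 0.0417). Their member Igfbp2, which binds growth factors, rose by 0.53 ± 0.03.

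Glutamate receptors and transporters were lower at 24 h for 13 of 22 and higher for 3, and adjusted over the list alone for 14 and 3 (-0.25 against all genes, adjusted p = 0.000854). Gria1, a subunit of AMPA receptors, fell by 0.55 ± 0.07 and Grin2b, a subunit of NMDA receptors, fell by 0.37 ± 0.05. With the mean of the probes of each gene the list no longer passed (adjusted p = 0.0718), and Grin2b was -0.087 (adjusted p = 0.461). GABA receptors and synthesis were lower for 13 of 20 and higher for 2, and adjusted over the list alone for 14 and 3 (-0.18 against all genes, adjusted p = 0.00352). Voltage-gated channels were lower for 9 of 23 and higher for 1 (-0.12 against all genes, adjusted p = 0.00958), with the potassium channel Kcnq5 falling by 0.74 ± 0.06 and the sodium channel Scn8a falling by 0.38 ± 0.03. Markers of hippocampal excitatory neurons were lower for 9 of 16 and higher for 1 (-0.21 against all genes, adjusted p = 0.000418), among them C1ql2 of granule cells, which fell by 0.67 ± 0.04. Interneuron markers were lower for 6 of 15 and higher for 2 (adjusted p = 0.0357, and adjusted p = 0.0652 with an estimated correlation). Tac1, the 1 member at least 2-fold lower, fell by 1.38. Pvalb, of fast-spiking cells, fell by 0.41 ± 0.04, while the neuropeptide Npy rose by 0.29 ± 0.03. This list no longer passed under quantile normalization (adjusted p = 0.094). Beside these neuronal groups, the 5 striatal genes among the neighbouring regions, a split made after the values were seen, had their highest mean in the saline 24 h group, with Adora2a there 2.59 and Rgs9 1.68 log2 units above the next group. Over 6461 genes with probes at separate places, the median of the 5' minus the 3' probe also differed, at 0.09 in saline 24 h and 0.16 in LPS 24 h. The whole list of neighbouring regions had 7 of 17 higher and 7 lower (adjusted p = 0.282). Within it the 5 striatal genes had lower means in LPS 24 h than in saline 24 h. The 7 thalamic genes, split off in the same way, had higher means there, except Tnnt1. Prkcd stood at 1.515 in LPS 24 h and 0.231 in saline 24 h, Ramp3 at 0.515 and 0.016, and Tnnt1 at -0.277 and -0.128. Whether tissue content enters the neuronal changes at 24 h was not tested.

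Immediate early and activity-regulated genes were higher at 24 h for 10 of 19 and lower for 3, and adjusted over the list alone for 12 and 3 (adjusted p = 0.0282, and adjusted p = 0.107 with an estimated correlation). Npas4, a transcription factor induced by calcium entry, rose by 1.61 ± 0.05 and Fos by 0.75 ± 0.03. Oxidative stress and kynurenine genes were higher for 8 of 13 and lower for 2, of which Ido1 was 1 (adjusted p = 0.0197, and adjusted p = 0.0716 with an estimated correlation). Ncf1, a subunit of the NADPH oxidase of phagocytes, rose by 1.15 ± 0.07. Heat shock and ER stress genes were higher for 7 of 16 and lower for 1 (adjusted p = 0.0427, and adjusted p = 0.0703 with an estimated correlation), with the small heat shock protein Hspb1 at 1.44 ± 0.04. The list no longer passed with slide as a block (adjusted p = 0.0549) or without saline 24 h replicate 2, LPS 24 h replicate 2 or LPS 24 h replicate 3 (0.0527, 0.0505 and 0.0515). Oligodendrocyte markers were lower for 5 of 12 and higher for 0 (adjusted p = 0.0433, and adjusted p = 0.0718 with an estimated correlation). This call was lost with the deposited matrix (adjusted p = 0.103) and without saline 24 h replicate 3, LPS 24 h replicate 1 or LPS 24 h replicate 2 (0.0551, 0.0648 and 0.0670). Precursors of oligodendrocytes (3 of 10 higher, 3 lower, median 0.01 and mean -0.04), cholesterol synthesis (2 of 16 higher, 6 lower) and the circadian clock (3 of 15 higher, 9 lower, and adjusted over the list alone 4 and 9) had adjusted p values of 0.812, 0.150 and 0.142. Gpr17, a receptor of the precursors, fell by 0.45 ± 0.06, Fdps, an enzyme of isoprenoid synthesis, fell by 0.33 ± 0.03 and the clock regulator Tef fell by 0.38 ± 0.05. With the mean of its probes Tef was -0.274 (adjusted p = 0.109). In all, 22 of 34 lists were higher and 7 lower at 24 h, of which 17 and 4 held with an estimated correlation. Against the saline arrays of 4 h in place of those of 24 h, a comparison added after the data were seen, voltage-gated channels were the 1 list that passed, and they were higher (adjusted p = 0.000628). Saa3 and Lcn2 stayed higher there, at 5.61 and 3.74, and Gfap turned lower, at -1.31. Called lower there, against the direction given above, were also Icam1 (-1.67), Bcl3 (-1.55), Tlr2 (-0.813), Cd14 (-1.11), Iigp1 (-0.451), C3 (-0.739), Socs3 (-0.307), Mt1 (-0.563), Fos (-1.90), Spp1 (-0.817), Tmem119 (-0.457), Aif1 (-1.46), Cnn1 (-0.190), Cd8b1 (-1.62), Cd79b (-0.919) and Igfbp2 (-0.338). Adora2a (0.388), Tac1 (0.344), Kcnq5 (1.02) and C1ql2 (1.40) turned higher. Ifi44, Phf11a, Cxcl10, Zbp1, H2-D1, Plin4, Ncf1, Scn8a, Pvalb and Npy were called in neither direction, at adjusted p values of 0.133 to 0.914.

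**Figure D2:**
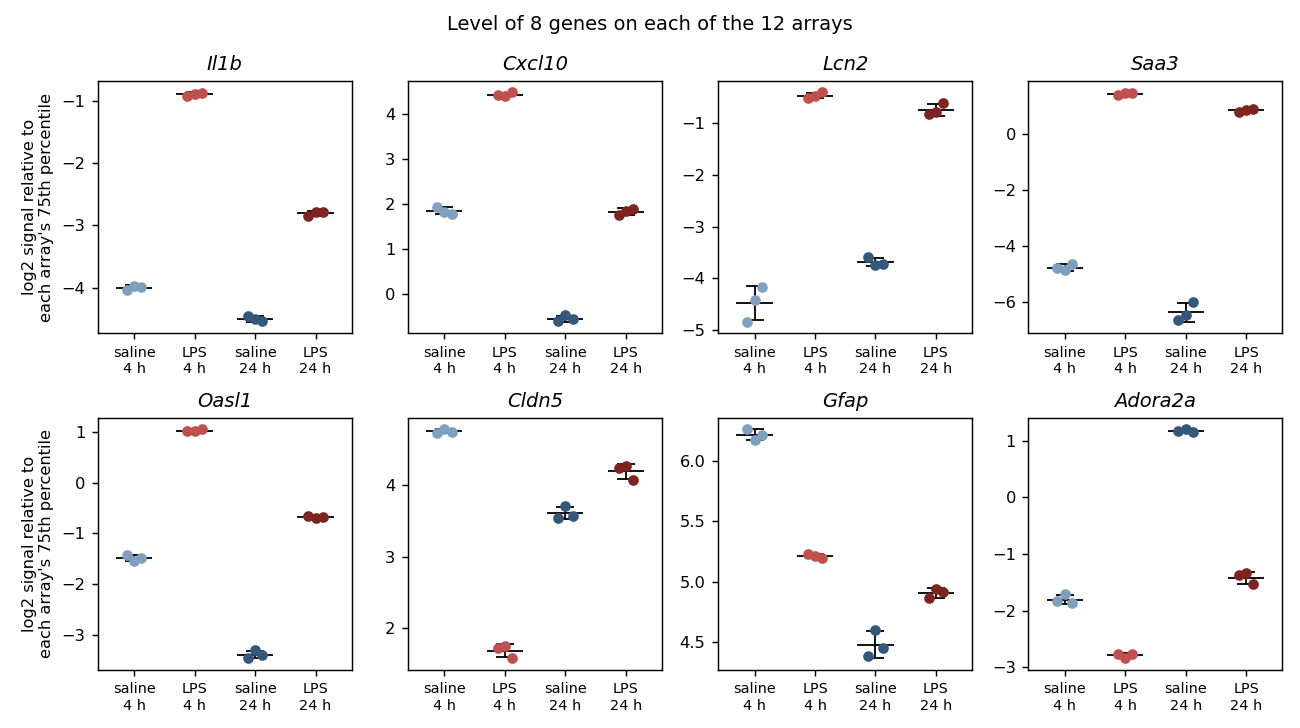
Log2 signal of 8 genes, relative to the 75th percentile of each array, on each of the 12 arrays (points), with the mean and SD of the 3 arrays per group (lines and bars). Il1b, Cxcl10, Lcn2 and Saa3 are higher in LPS than in saline at both times, Cldn5 falls by 3.08 at 4 h, and Adora2a is highest in saline 24 h.

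The third comparison tests whether the response to LPS differed between the times. Endothelial genes were higher at 24 h relative to 4 h, and neuronal channels and glutamate receptors were lower. Akap12, which rose at 4 h and was measured on all arrays, moved down by 4.10 ± 0.06 (n = 3 per group, adjusted p = 5.79e-10). Sox17, which fell at 4 h and was also measured on all arrays, moved up by 3.83 ± 0.08 (adjusted p = 1.06e-09). Csf3 and Cxcl1 moved down as well, with adjusted p values of 1.79e-09 and 1.14e-07, and no size is given because they were below background in 3 and 2 of the 4 groups. The response differed for 12535 of 18179 genes, 7731 upward and 4804 downward. At least 2-fold, 1646 went up and 1415 down, and with the deposited matrix this split was 527 up and 689 down.

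Of the lists, voltage-gated channels had 15 of 23 members lower and 2 higher in the difference (-1.04 against all genes, adjusted p = 0.000255), glutamate receptors and transporters 16 of 22 lower and 2 higher (-0.63, adjusted p = 0.000475), and endothelium and blood-brain barrier 15 of 19 higher and 1 lower (0.77, adjusted p = 0.000691). These 3 calls held with an estimated correlation, at an adjusted p of 0.0275 each. Complement (11 of 15 higher, 1 lower, adjusted p = 0.00514), excitatory neurons (12 of 16 lower, 4 higher, adjusted p = 0.00514), glucocorticoid response (11 of 17 lower, 4 higher, adjusted p = 0.0191) and choroid plexus and ependyma (11 of 13 higher, 1 lower, adjusted p = 0.0232) had adjusted p values of 0.0987, 0.0578, 0.172 and 0.0987 with an estimated correlation. Resting-state microglia (12 of 14 higher, 2 lower, adjusted p = 0.0436), interneurons (9 of 15 lower, 4 higher, adjusted p = 0.0436) and JAK-STAT feedback (8 of 15 lower, 4 higher, adjusted p = 0.0442) each had an adjusted p of 0.117 with an estimated correlation. With slide as a block these 3 calls were lost as well (adjusted p values of 0.0672, 0.0671 and 0.06). The cytokine list, with 8 of 20 higher and 8 lower, did not pass (adjusted p = 0.792).

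Calls in the same direction at both times numbered 1352 for higher genes, where independent lists would share 1242, and 1860 for lower genes, where they would share 1842. Of the genes at least 2-fold higher, 154 were so at both times, 3.85 times the 40.03 of independent lists, and of those at least 2-fold lower 9 were, against 1.87. Calls in opposite directions were more frequent than those in the same direction: 1569 of the genes higher at 4 h were lower at 24 h, and 2074 of those lower at 4 h were higher at 24 h. Of the genes at least 2-fold lower at 4 h, 42 were at least 2-fold higher at 24 h, and 3 went from higher to lower. Across the 18179 genes, which are not independent replicates, the responses at the 2 times had a Pearson correlation of 0.066 and a Spearman correlation of -0.0575.

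**Figure D3:**
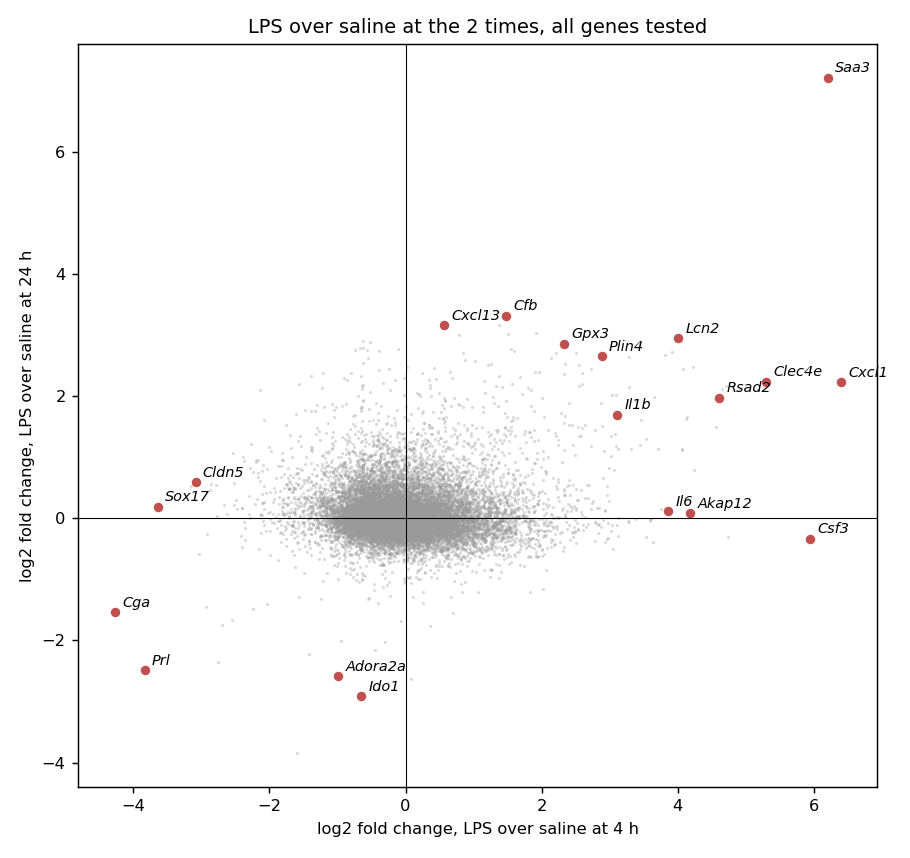
Log2 fold change of LPS over saline at 4 h (x axis) and 24 h (y axis) for all 18179 genes (grey points), with some named genes in red. Il1b lies at 3.11 and 1.70, Plin4 at 2.88 and 2.66 and Akap12 at 4.18 and 0.08. The places of genes below background in a group, such as Saa3 and Cxcl1, are fitted values and no measured folds.

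The last comparison describes the control mice, saline at 24 h against saline at 4 h. Genes of cytokines and chemokines and of the interferon response were lower at 24 h as lists, and voltage-gated channel genes were higher. The chemokine Ccl5 fell by 3.92 ± 0.04 and Gpr151, a receptor enriched in the habenula, fell by 3.95 ± 0.09 (n = 3 per group, adjusted p values of 4.18e-12 and 1.02e-10). The milk protein gene Wfdc18, the ribosomal protein gene Rpl39l and Ripor3 made up the rest of the 5 largest fitted falls, at -3.94 ± 0.06, at least 14.0-fold lower and at least 6.36-fold lower (adjusted p values of 1.69e-11, 1.54e-09 and 9.21e-08). The largest fitted rises were the mitochondrial tRNA ligase Lars2 (5.61 ± 0.10) and Dio3, which inactivates thyroid hormone (4.70 ± 0.05), with adjusted p values of 2.87e-11 and 5.37e-12. They were joined by the auxiliary AMPA receptor subunit Cacng8 (at least 13.2-fold), the histone methyltransferase Kmt2d (at least 5.67-fold) and Nhsl2 (at least 4.08-fold), with adjusted p values between 5.85e-12 and 1.08e-08.

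Between the saline groups 14684 genes differed, 5872 higher and 8812 lower at 24 h, with 2170 and 2965 at least 2-fold, more than in either LPS comparison. With normexp background correction and the same scaling, 3599 were higher and 10918 lower. Lists that were lower at 24 h and held with an estimated correlation were cytokines and chemokines (17 of 20 lower, 0 higher, adjusted p = 0.000975), type I interferon response (23 of 24 lower, 1 higher, adjusted p = 8.11e-05), interferon gamma and antigen presentation (16 of 19 lower, 1 higher, adjusted p = 0.00162), microglia and macrophage activation (14 of 18 lower, 2 higher, adjusted p = 0.00711) and reactive astrocytes (18 of 24 lower, 3 higher, adjusted p = 0.0111). Voltage-gated channels (21 of 23 higher, 1 lower, adjusted p = 5.39e-06) and interneurons (13 of 15 higher, 2 lower, adjusted p = 0.00168) were higher and also held. Of 14 lists called in this comparison, 5 higher and 9 lower, 2 and 5 held. Immediate early genes were lower for 14 of 19 and higher for 4 (adjusted p = 0.0369, and adjusted p = 0.176 with an estimated correlation), with Fos falling by 2.64 ± 0.03. NF-kappaB targets (13 of 17 lower, 2 higher, adjusted p = 0.0245), complement (12 of 15 lower, 3 higher, adjusted p = 0.0289) and the glucocorticoid response (15 of 17 lower, 1 higher, adjusted p = 0.00317) had adjusted p values of 0.102, 0.127 and 0.106 with an estimated correlation. Glutamate receptors and transporters (11 of 22 higher, 5 lower, adjusted p = 0.048), GABA receptors and synthesis (14 of 20 higher, 6 lower, adjusted p = 0.0225) and excitatory neurons (10 of 16 higher, 5 lower, adjusted p = 0.0289) had 0.103, 0.0725 and 0.0939. Of 7 thalamic genes among the neighbouring regions, 5 had higher means in both 4 h groups than in both 24 h groups, the exceptions being Lef1 and Slc17a6. Among 6461 genes with probes at separate places, the 5' minus the 3' probe was taken relative to each gene's mean over the 12 arrays. Its median was -0.11 in saline 4 h and -0.13 in LPS 4 h, against 0.09 in saline 24 h and 0.16 in LPS 24 h. These signs place the groups relative to each other and do not tell which probe was brighter. The groups of this comparison were scanned in different runs, and no array of one time was in the run of the other, so run and time cannot be told apart.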

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

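The tests of 8 explanations given here were chosen after the values were seen, and the 4 tests of other splits of the arrays were planned before.

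The response to LPS differed between 24 h and 4 h for 12535 genes by a test of the difference itself, which is what brought the results here to attention. Random splits of the arrays within each time, 100 in all with the real one, gave at most 9649 genes in the others. The real split, 1 of 100, gave as many as 12535. These splits ignore the slides and break the LPS effect itself, in part in the split with 9649 genes. They do not test whether the responses at the 2 times were equal, and no conclusion about chance is drawn from them. That the arrays are separate animals rests on the labels. For LPS against saline at 4 h the real split gave 13413 genes and the highest of the others 32, at 24 h 8382 and 1, and for the saline groups 14684 and 0. In each of these 3 comparisons 1 of the 10 splits gave as many genes, and 10 splits are too few for a share under 0.05.

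The single genes named here had the largest fitted differences of each sign among genes with a plain symbol. Downward, 24 h minus 4 h, these were Csf3 (-6.28), the chemokine Cxcl1 (-4.17), Akap12 (-4.10), Kmt2d (-4.02), Slfn4, a Schlafen gene induced by interferon (-3.84), and Il6 (-3.75). Upward they were the granzyme Gzmc (4.23), endothelial Sox17 (3.83), the muscle gene Abra (3.76), Rpl39l (3.72), the transcription factor Tcf23 (3.69) and endothelial Myct1 (3.68). Csf3, Slfn4 and Il6 were below background in both groups at 24 h and Cxcl1 in both saline groups, and Kmt2d, Gzmc, Rpl39l and Myct1 were so in at least 1 group, so their values are neither folds nor bounds and give no rank. With normexp and the 75th percentile Gzmc (0.783) and Slfn4 (-0.591) no longer passed, at adjusted p values of 0.107 and 0.0662.

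Lists whose response differed by the same test had these median differences: voltage-gated channels -0.85, glutamate receptors and transporters -0.45, excitatory neurons -0.75, interneurons -0.63, JAK-STAT feedback and IL-6 family receptors -0.62 and the glucocorticoid response -0.31. Upward were complement at 1.12, endothelium and the blood-brain barrier at 0.96, choroid plexus and ependyma at 0.92 and resting-state microglia at 0.48. With an estimated correlation the calls of voltage-gated channels, glutamate receptors and endothelium held, and the other 7 were lost, at adjusted p values of 0.0578 to 0.172. The median of all genes was 0.19 in this comparison.

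Striatal genes such as Adora2a, Drd1 and Rgs9 fell after LPS at 24 h. Of the 5 striatal markers, all 5 had their highest mean in the saline 24 h group, so striatal tissue in those samples may be the source. Adora2a stood at 1.17 there relative to the 75th percentile and at -1.80 in saline 4 h. Lowering by LPS in the sampled tissue predicts LPS 24 h values below those of other saline mice, and the median of LPS 24 h minus saline 4 h was 0.39. The predicted fall was thus not seen in the median. Drd1 was lower (-0.884), while Rgs9, Adora2a, Drd2 and Ppp1r1b were not (0.005 to 1.43). Because these values compare animals across scan runs, lowering by LPS cannot be told apart from a difference in tissue.

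Endothelial genes such as Cldn5 and Tek were lower 4 h after LPS. A smaller share of endothelial cells would lower all 19 members of the list by about the same amount if endothelium alone expressed them. Their changes ran from -3.08 to 1.04 with an SD of 1.02 against a median SE of 0.04. On that condition, which was not tested, this argues against a smaller share as the whole cause. Saline 4 h arrays that stood apart from the other groups stay open: against saline 24 h the median of the 19 members was -0.36, with 11 lower and 8 higher, and the list did not pass (adjusted p = 0.119). Cldn5 and Tek themselves stayed below saline 24 h, at -1.93 and -2.29, against -3.08 and -2.52 with saline 4 h. That comparison crosses scan runs. It cannot tell how far a saline 4 h group that stood apart accounts for the fall of these single genes. For the list as a set, regulation by LPS cannot be told apart from such a saline 4 h group with these arrays.

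Voltage-gated channel genes, such as Kcnq5, were lower in saline 4 h than in LPS 4 h and saline 24 h. Loss of 5' ends in the saline 4 h samples is argued against for the LPS comparison, where the 5' minus 3' median differed by 0.017, but not for saline 24 h, where it differed by -0.19, a difference that goes along with the scan run. Scaling of the dimmer arrays could be part of it. The list's own median at 4 h was 0.685, and 0.34 after normexp with quantile normalization. The medians of all genes were -0.149 and -0.042 in these settings, and signal level goes with the group. The state or tissue content of the saline 4 h animals needs the list to differ between the saline groups (its own median was 1.22). For that difference it cannot be told apart from the run. Within the run of 4 h, the list was 0.80, 0.69 and 0.79 above all genes on the slides, where the run does not enter. There the state or tissue content cannot be told apart from a response to LPS.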

How the results depend on the processing

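Other settings were chosen before the data were examined, except the exchange of saline groups, which was chosen after seeing them. A call is kept here when direction and side of the threshold stay, and a sign that turned while neither value passed also counts as kept. Of the 136 list results, 127 kept their call with quantile normalization, 127 with normexp and quantile normalization, 129 with normexp and the 75th percentile, 126 with the deposited matrix, 130 when detected on all arrays and 129 with the mean of the probes. Of 330 values of named genes, 327, 322, 306, 321, 276 (fewer are measured) and 317 did so, and with array weights all 136 and 330 did. Signal over background limits the sizes: genes below background in saline have lower bounds only. Where no cause is given, the cause was not tested.

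Requiring at least 2-fold left 2155 genes at 4 h, 583 at 24 h, 3061 for the difference, 5135 between the saline groups and 163 shared between times, by construction. These 2-fold counts fell with other background corrections and scalings, in the order 4 h, 24 h, difference and saline: 759, 169, 1236 and 2298 with normexp and quantile normalization, 751, 188, 1286 and 3244 with normexp and the 75th percentile, and 746, 170, 1216 and 2277 with the deposited matrix. They were 1418 at 4 h and 327 at 24 h for genes detected on all arrays, where fewer genes are tested, and without a filter 888 at 24 h and 11201 between the saline groups. Without the 2-fold condition, normexp and the 75th percentile gave 3410 at 24 h and 7790 for the difference. Shared calls numbered 2013 with normexp and quantile normalization, 1040 with normexp and the 75th percentile, 2091 with the deposited matrix and 2098 at an adjusted p under 0.01.

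At an adjusted p under 0.01, 11 lists were called at 4 h, 5 for the difference and 7 between the saline groups. With an estimated correlation these were 11, 3 and 7, and without a filter 17 for the difference.

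Single genes turned their sign at 4 h: C1qc was 0.028 with normexp and quantile normalization, and Nrgn 0.17 with quantile normalization, 0.14 with normexp added and 0.12 with the deposited matrix. With the mean of the probes Acta2 was -0.115 and Tcf7l2 0.105 at 4 h, and Gria3 0.091 and Pdgfra 0.22 at 24 h, where single probes differ. Tnf at 4 h was -0.015 with normexp and the 75th percentile.

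With the saline groups exchanged, 14724 genes differed at 24 h, 4870 of them at least 2-fold (2339 higher, 2531 lower), and 1 list was called. The direction that camera gives, relative to other genes, turned at 4 h for the lists that follow, with their medians after the exchange: immediate early genes (0.71), glutamate receptors (0.038), GABA receptors (-0.24), voltage-gated channels (-0.70), excitatory neurons (-0.22) and interneurons (-0.265). At 24 h it turned for cytokines (-0.24), NF-kappaB targets (-0.445), interferon gamma (-0.451), endothelial activation (-0.29), glucocorticoid response (-0.48), oxidative stress (-0.44), immediate early genes (-1.03), glutamate receptors (-0.15), GABA receptors (0.37), voltage-gated channels (0.885), resting microglia (-0.44), activated microglia (-0.54), excitatory neurons (0.25), interneurons (0.34) and lymphocytes (0.053). The medians themselves kept their sign for glutamate receptors at both times and for lymphocytes. Of 152 named genes changed at 4 h, 95 passed in the same direction, 45 in the opposite one and 12 did not pass, and of 153 at 24 h these were 84, 48 and 21. Of all genes at least 2-fold higher at 4 h, 341 of 1345 were so after the exchange and 399 were called opposite, and of those lower 85 of 810 and 415. At 24 h these were 133 of 541 and 141 for higher genes and 17 of 42 and 9 for lower genes. The run confounded with time enters these values.

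Leaving out each array in turn gave 12820 to 13197 genes at 4 h (2106 to 2289 at least 2-fold, 16 to 17 lists), 7380 to 8218 at 24 h (561 to 586, 27 to 29), 12109 to 12509 for the difference (2982 to 3226, 7 to 11), 14216 to 14412 between the saline groups (5077 to 5190, 13 to 14) and 2815 to 3177 shared calls. Beyond the lists named with the comparisons, calls for the difference were lost for JAK-STAT feedback without saline 4 h replicate 2 or 3, LPS 4 h replicate 1, saline 24 h replicate 3 or LPS 24 h replicate 2 (adjusted p values of 0.051 to 0.0664). They were lost for resting microglia without LPS 4 h replicate 1 (0.0508) or LPS 24 h replicate 2 (0.0506) and for interneurons without saline 4 h replicate 2 (0.0549) or LPS 4 h replicate 1 (0.0528), and gained for GABA receptors without LPS 24 h replicate 3 (0.0471). Between the saline groups glutamate receptors were lost without saline 4 h replicate 2 (0.0642) or saline 24 h replicate 3 (0.0618).

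Correlations of arrays with equal replicate numbers ran from -0.16 to 0.19 at 4 h, so the numbers do not pair those arrays. At 24 h equal numbers share a slide, and correlated at 0.073 to 0.104, against -0.076 to -0.024 for the others. With slide as a block 6 list calls were lost: at 24 h heat shock (0.0549), oligodendrocytes (0.0615) and interneurons (0.0608), and for the difference JAK-STAT feedback (0.06), resting microglia (0.0672) and interneurons (0.0671). With the replicate number as a block, 13256 genes passed at 4 h, 7974 at 24 h, 12394 for the difference and 14560 between the saline groups, and 1 list was lost, oligodendrocytes at 24 h (adjusted p = 0.0548). No values exist for lists with every probe tested or with the 2-fold condition, nor for the saline comparison with slide as a block.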

Other observations

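Some genes stood apart between the saline groups as much as after LPS, n = 3 arrays per group. From saline 4 h to saline 24 h, Spp1, which encodes osteopontin, fell by 2.54 ± 0.03, C1qc, a chain of the first complement component, fell by 2.16 ± 0.03, and Gfap fell by 1.73 ± 0.05, with adjusted p values of 5.85e-12, 1.42e-11 and 4.89e-10. The interneuron peptide gene Sst was higher at 24 h by 2.44 ± 0.03 (adjusted p = 1.17e-11). Of the activity-regulated genes, Egr4 fell by 2.93 ± 0.05 and Bdnf fell by 1.70 ± 0.04 (adjusted p values of 1.94e-11 and 5.77e-11).

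The sign after LPS followed the saline group for some genes, in a comparison added after the data were seen. Itgam, the CD11b integrin of myeloid cells, was -0.57 ± 0.03 at 4 h against saline 4 h but 0.738 against saline 24 h, and at 24 h it was 0.74 ± 0.03 against saline 24 h but -0.567 against saline 4 h. Nos1, the neuronal nitric oxide synthase, was 0.84 ± 0.04 and -0.58 at 4 h, and -0.51 ± 0.04 and 0.907 at 24 h, in the same order. All 8 values passed the test, with adjusted p values up to 2.52e-06.

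Across all genes, the response at 4 h and the difference of saline 24 h from saline 4 h, which share the saline 4 h arrays, had a correlation of 0.609 and a covariance of 0.428. Data simulated with no effect gave 0.495 and 0.0128. The median SD between the 3 arrays of a group was 0.0436 in saline 4 h, 0.0405 in LPS 4 h, 0.0579 in saline 24 h and 0.0616 in LPS 24 h over 14687 genes. Between the repeated spots of 163 probes on a single array it ran from 0.0514 to 0.0883. For immediate early and activity-regulated genes the median SD was 0.0475 within groups and 0.658 between the means of the groups. Over all 14687 genes these were 0.0503 and 0.364.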
